A study of Drosophila melanogaster with 2 samples.

How the data were processed

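Whole embryos of transgenic flies aged 0 to 24 h were used for chromatin immunoprecipitation with an antibody to GFP, per the labels, in 1 group of 2 biological replicates. The antibody field of the labels names rib, while their description names an anti-GFP antibody and a rib-eGFP fusion. Chromatin was sonicated to fragments of 200 to 800 bp. The labels name a possible control experiment, whose data were not among those used here. No background measured in control samples could therefore be set beside the values. The aligner, the peak caller and their versions are not given in the sources used here.

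The authors deposited, for each replicate and for the series, lists of ranked regions and lists of peaks past a threshold on the irreproducible discovery rate (IDR), with a conservative list besides for the series, all on dm6. The signal in the deposited lists is the peak caller's own measure of peak strength. Its scaling is not stated, so it was compared only within a list or, between replicates, as a ratio relative to other genes. The score in the deposited lists was tested on the values and is the IDR rescaled to whole numbers, where 830 or more stands for an IDR of 0.01 or less. The ranked lists deposited by the authors also hold the global IDR as its negative log10 (neg log10 p in form), which was used to read the score. The lists hold no read counts, so depth is unknown and the intervals cover counting of peaks and genes only. Positions in the lists count from 0 and were moved to count from 1.

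Peaks were assigned with the Ensembl release 115 annotation (BDGP6.54) and sequence was taken from the Release 6 assembly, on arms 2L, 2R, 3L, 3R, 4, X and Y. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9. The series list of 4606 thresholded peaks was the set used throughout, except for the comparison of the replicates. Peaks were shared when they overlapped by at least 1 bp. Correlations of signal were across peaks, without a p, since peaks are not replicates.

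The share of summits within 500 bp of a protein-coding TSS was tested with a two-sided exact binomial test against the share of bases in those windows. Shares of arms were tested the same way against shares of TSSs. For 24 gene lists, genes with a summit within 500 bp of any TSS were counted against all other protein-coding genes with Fisher's exact test, two-sided. Lists overlap in part: rib is in both the BTB and the salivary gland list, and ush in both the tracheal list and the gut, fat body and hemocyte list. An odds ratio with an empty cell that would be infinite was computed with 0.5 added to each cell. Mean log2 signal of the highest peak per bound gene was compared between a list and other bound genes, for lists with at least 5 bound genes, with a two-sided permutation test of 100000 resamples. Complete enumeration had been planned for lists under 10 genes but is not feasible against all other bound genes, so resampling was used there too.

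For 16 motifs, presence within 50 bp of the summit on either strand was set against a flank of equal length 250 bp away with an exact McNemar test, two-sided. At promoters, summits were set against positions at the same offset from TSSs without a peak within 1000 bp, 3 per summit, with Fisher's exact test, and every 7-mer with its reverse complement was tested the same way. Control positions were drawn at random and can repeat. P-values were adjusted by the Benjamini-Hochberg method within each family, and the threshold was an adjusted p of 0.05. The steps were tested on simulated data: 3 of 3 lists made enriched, 2 of 2 made depleted, and the planted motif and 7-mers were called. So was 1 of the 19 lists left alone, for binding and again for signal, and in repeated draws with nothing changed 3 of 480 lists were called for binding and 0 of 98 for signal.

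Lists, motifs, tests, main alternatives and the rule for named genes were set before the data were examined. The rule named rib, the genes nearest to the 20 strongest peaks, the 4 strongest bound genes and up to 3 unbound genes in alphabetical order of each called list, up to 2 bound genes of every other list, and trh, btl, vvl, fkh, sage and CrebA. Of the genes so named, 1 is not reported here. Called motifs and the 10 7-mers with the smallest p were named as well. Later, but before any list was tested, a symbol that resolved to another gene was taken out of the gut, fat body and hemocyte list and Cp110 and Cp190 out of the chorion list. The pattern for ribosomal proteins misses symbols with a hyphen. Alternatives were the conservative list, the stronger 50% of peaks, each replicate's own list, other windows, the nearest TSS alone, other TSS sets, expected shares by bases, a pair of housekeeping backgrounds, other word lengths and other rules for shared peaks. The background of genes with a core promoter element (within 100 bp of a TSS) restricts both the list and the other genes to 5005 genes with such an element. The 2000 strongest peaks of each replicate, and for arms all ranked regions of the series with a score of 830 or more, were added as alternatives after the data were seen. Measurements could be affected by promoters that are open in many cells and bind many antibodies, by repeated sequence, by copies carried by the transgene and by the tag. Between replicates, leaving out replicate 1 means using the list of replicate 2, which has fewer peaks.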

Results

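Chromatin immunoprecipitation followed by sequencing was done on whole Drosophila melanogaster embryos aged 0 to 24 h that carried a transgene for rib fused to eGFP, a green fluorescent protein. The precipitation used an antibody to GFP. The gene rib (ribbon) encodes a nuclear protein with a BTB domain, and embryos without it form misshapen tracheae and salivary glands. There was 1 group of 2 biological replicates and no group to compare it with. The deposited data are lists of peaks, so the sequencing depth of either replicate is unknown. Replicate 1 had 3082 peaks past the irreproducible discovery rate (IDR) threshold and replicate 2 had 2181. The list called from both replicates held 4606 peaks with a median width of 380 bp. A separate conservative list held 3959. Of these, 3561 (89.9%) overlapped a peak of the 4606, so it is not a subset of them. The median signal of the 4606 peaks was 93.2 in the peak caller's own unit, with quartiles at 75.2 and 129 and a maximum of 1732. Each signal in this list is a single pooled value without a replicate error. All positions are on the dm6 assembly, counted from 1.

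The strongest peak in the genome lay beside rib itself. It had a signal of 1732, and its summit at 2R 19268981 was in intergenic sequence 1097 bp upstream of the rib start. A further peak at rank 6 had a signal of 1049 and lay at 2R 19275539, in an intron and 193 bp upstream of the second annotated start of rib. In all, 33 peaks fell within 20 kb of the gene (2R 19270078 to 19281396), where the average density over the chromosome arms gives 1.72. Of these, 21 overlapped peaks of both replicates. The labels name an insertion that targets rib, and sequence that the transgene carries from this region is precipitated and sequenced in the same way as the resident copy.

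**Figure D1:**
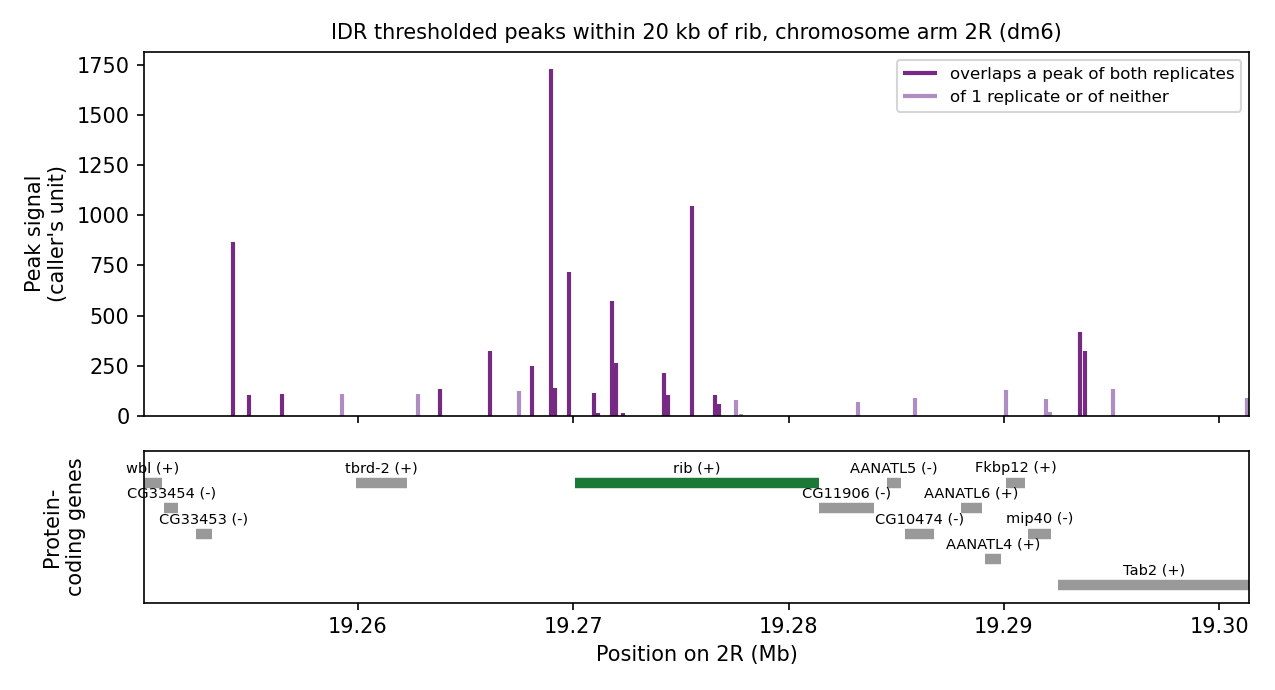
Signal of the IDR thresholded peaks within 20 kb of rib on 2R, in the peak caller's unit, above the protein-coding genes with their strands. Dark bars overlap a peak of both replicates, and the highest bar, at 1732, lies upstream of rib.

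The strongest peaks away from rib lay near genes of varied function. Of the 20 strongest peaks, those at rib included, 13 had their summit within 500 bp of a transcription start site (TSS), 9 of them up to 200 bp upstream, and all 20 overlapped peaks of both replicates. The summit 40 bp upstream of Ugalt, a transporter of UDP-galactose into the Golgi, had a signal of 1503. The summit at 2R 15217742, just upstream of mRpL41, a protein of the mitochondrial ribosome, had 1253. Tcs5, a kinase of the complex that modifies tRNA (signal 990, 108 bp upstream), and eIF6, which keeps large ribosomal subunits free (880, 112 bp upstream), followed. Art3, an arginine methyltransferase, had 869 at 126 bp upstream, and CenG1A, which regulates Arf GTPases, had 859 at 96 bp upstream. The peak of PNPase, which degrades RNA in mitochondria, had 732, and that of the mitochondrial ribosomal protein gene mRpL23 had 731. Genes for chromatin proteins were also near. The peak 491 bp upstream of a start of ph-p, a Polycomb group gene, had a signal of 907, and a peak in an intron of Trl, which encodes GAGA factor, had 740. The peak in the 5′ UTR of caps, which encodes a cell-surface protein of tracheal and neural cells, had 750. The other genes nearest to the 20 strongest peaks were the little-characterised CG11050 (1641, in an intron), CG14100 (1342), CG33453 (869), CG5611 (829), CG4004 (811), CG32772 (785) and CG3726 (749). CG33453 lies within 20 kb of rib, with tbrd-2 between them, and its peak is 1 of the 3 strongest within that distance.

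Most of the strongest sites were found in both replicates. Of the 100 strongest peaks of each replicate, 75 overlapped (95% exact interval 65.3% to 83.1%), and of the 500 and 2000 strongest, 325 and 1259. Over the whole lists, 1575 of the 3082 peaks of replicate 1 overlapped a peak of replicate 2, which is 51.1% (exact interval 49.3% to 52.9%). From the other side, 1537 of 2181 peaks were shared, or 70.5% (68.5% to 72.4%). Among the 4606 peaks of the joint list, 1578 (34.3%) overlapped peaks of both replicates and 1252 (27.2%) a peak of neither. Across 4579 peaks found in both ranked lists, log2 signal had a Pearson r of 0.47 and a Spearman rho of 0.42, where peaks are not independent replicates. In the conservative list r was 0.71 and rho 0.51.

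Peaks sat at promoters far more often than chance placement gives, which addresses where on genes the tagged protein was recovered. Of 4606 summits, 2395 lay within 500 bp of a TSS of a protein-coding gene, or 52.0% (95% exact interval 50.5% to 53.4%), while such windows cover 11.2% of the bases of the arms. The ratio was 4.66, with a two-sided exact binomial p below the smallest number the software can hold. The share was 62.0% among the 100 strongest peaks and 47.5% among the weaker 50%. Summits gathered just upstream of starts: 1416 were upstream and 979 at or downstream, and 1917 (41.6%) lay within 200 bp. In 5′ UTRs, which cover 2.98% of bases, lay 922 summits, 6.71 times the share of bases. Coding exons held 3.60% of summits against 16.6% of bases. Without replicate 1 the promoter share was 55.4%, and without replicate 2 it was 54.2%.

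**Figure D2:**
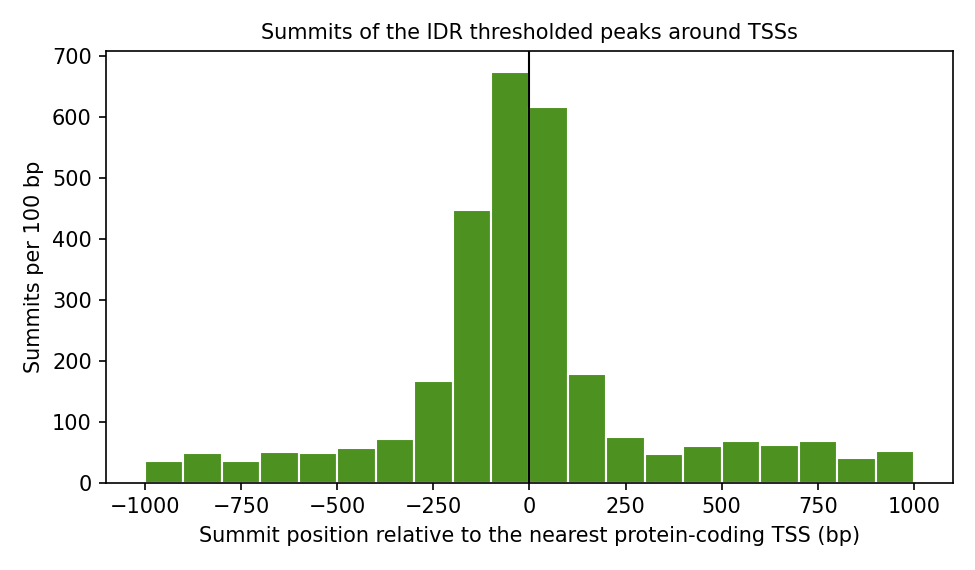
Number of summits of the IDR thresholded peaks per 100 bp around the nearest TSS of a protein-coding gene, with negative positions upstream. The highest bar is the 100 bp just upstream of the TSS, with 674 summits.

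The share of peaks departed from the share of TSSs on 6 of 7 arms, of which 4 were left when all ranked regions past the score were counted. Arm 3L held 1033 peaks, 1.16 times its share of TSSs (exact binomial test, adjusted p 1.08e-06 over 7 arms), and 2R held 1.08 times its share (adjusted p 0.00993). The X held 0.870 times its share (adjusted p 1.85e-04), 3R 0.923 times (0.00656), and the small chromosome 4 held 16 peaks, 0.472 times its share (0.00231). No peak was on Y, where TSSs give 0.119% of peaks (adjusted p 0.00993). On 2L the ratio was 0.992 (adjusted p 0.806), and against its share of assembled bases it turned to 1.09, past the threshold, as were all 7 arms there. With the 172 regions that pass the score but are not in the thresholded list, 106 of them on 3R, the ratio of 3R was 0.984 and that of 2R 1.05, neither past the threshold. Without replicate 1, only the call for 3L was left, at a ratio of 1.13. Without replicate 2, those for 2R (1.05) and Y were lost. The test takes peaks as independent, but they came in groups, which makes its p too small. Of the 1014 peaks on 2R, 33 lay within 20 kb of rib, and on 3L 33 lay in or within 1 kb of Eip75B. The ratios without these groups were not computed.

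Genes for BTB domain transcription factors, glycolysis and ribosomal proteins were the groups bound most often at their starts. The question was whether the genes at which the protein was recovered belong to the organs that rib shapes, to the translation machinery, or to neither. A gene was called bound when a summit lay within 500 bp of any of its TSSs, and 2547 of 13968 protein-coding genes (18.2%) were bound. Of the 86 cytoplasmic ribosomal protein genes, 48 were bound, or 55.8% (exact interval 44.7% to 66.5%), with an odds ratio of 5.75 (95% interval 3.67 to 9.07; Fisher's exact test, adjusted p 1.34e-13 over 24 lists). The strongest peaks among them were at RpL7 (signal 366, 46 bp downstream of the TSS), RpL34b (272, 80 bp upstream), RpL32 (246, 123 bp upstream) and RpL23A (230, 88 bp upstream). RpL10, RpL10Aa and RpL12 were not bound. The list of replicate 2 had peaks at 41 of the 86 genes and that of replicate 1 at 26, and 21 genes were in both. The odds ratio was 7.76 without replicate 1 and 2.93 without replicate 2, past the threshold in each.

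Of the 16 BTB transcription factor genes, 13 were bound (odds ratio 19.5, interval 5.36 to 107, adjusted p 3.71e-07). Besides rib (1049), the strongest were at starts of Trl (284), of lola, which guides axons (232), and of Cp190, an insulator protein gene (209). The genes ab, bab1 and br, which act in neurons, limbs and ecdysone response, were not bound. The odds ratio was 8.36 without replicate 1 and 20.2 without replicate 2. The ribosomal protein and BTB lists were past the threshold under all 11 alternatives tried. Genes with several annotated starts had more chances to be called bound, and none of these alternatives allowed for the number of starts. The peaks given for Trl and lola lay at starts inside the gene.

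Genes of sugar breakdown were bound at 8 of 12 (odds ratio 8.99, interval 2.41 to 40.8, Fisher's exact test, adjusted p 0.00102). Gapdh2 had a signal of 602 at 154 bp upstream of its TSS, Eno 321, Hex-A 249 and Pgk 153, each in both replicates. Ald1, Pfk and PyK were not bound. With the list and the other genes both restricted to those with a housekeeping core promoter element, the odds ratio was 19.4 and no longer past the threshold.

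Genes known from tracheal development were bound at 18 of 40 (odds ratio 3.69, interval 1.86 to 7.21, adjusted p 3.49e-04). The strongest peaks were at conv, which organises the chitin of the tracheal lumen (signal 160), crb, which sets the apical membrane (146, 13 bp upstream of the TSS), ush, a cofactor of GATA factors (143), and pnt, an effector of receptor tyrosine kinases (135, not in replicate 2). Around the start of ush, 7 regions past the score (2L 472447 to 482004, highest signal 1045) are missing from the thresholded list and were not counted. Alk, Gasp and Mipp1 were not bound. The call rested on replicate 1, which had peaks at 15 of these genes against 6 in replicate 2. Without replicate 1 the odds ratio fell to 1.47, not past the threshold, and without replicate 2 it was 4.04. It was also lost in the conservative list (2.18), in the stronger 50% of peaks (1.93), and against both housekeeping backgrounds (3.17 and 2.12).

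Salivary gland genes were bound at 13 of 32 (odds ratio 3.08, interval 1.40 to 6.58, adjusted p 0.0111). After rib, the strongest peaks were at fkh, the forkhead factor that the gland needs to survive and invaginate (signal 215, 225 bp upstream of its TSS), klar, which moves organelles along microtubules (176), and ps, a splicing regulator of the gland (149). CrebA, Gprk2 and PH4alphaSG1 were not bound. Of the other regulators of these organs, trh, which specifies the trachea, vvl, a POU factor of the trachea, and sage, a bHLH factor of the gland, had no summit within 500 bp, and the nearest were 15978, 26266 and 27757 bp from a TSS. The nearest summit to btl, the FGF receptor that guides tracheal branches, was 3930 bp away with a signal of 103, and that to CrebA, which raises secretory capacity, was 2781 bp away with 103. Without replicate 1 the odds ratio of the gland list was 1.92, not past the threshold, and without replicate 2 it was 3.05. It was lost as well in the stronger 50% of peaks (2.57) and against both housekeeping backgrounds (2.31 and 1.77).

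Regulators of the cytoskeleton and apical membrane were bound at 15 of 37 (odds ratio 3.07, adjusted p 0.00556). The strongest peaks were at betaTub56D, a tubulin (signal 186), Myo31DF, a myosin that sets left-right asymmetry (184), sqh, the light chain of non-muscle myosin (157, not in replicate 2), and tsr, which severs actin filaments (154). Act42A, Cdc42 and Patj were not bound. The odds ratio was 2.30 without replicate 1, not past the threshold, 3.23 without replicate 2, and 1.14 and 1.77 against the housekeeping backgrounds, again not past it.

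Other parts of the translation machinery were bound more often than average by smaller margins. Translation factor genes were bound at 17 of 54 (odds ratio 2.07, interval 1.09 to 3.77, adjusted p 0.0432), with eIF6 (880), pAbp, which coats poly(A) tails (274), eIF3h (263) and eEF1gamma (188) the strongest. The elongation factor genes eEF1alpha2, eEF1beta and eEF1delta were not bound. Genes of ribosome biogenesis were bound at 12 of 32 (odds ratio 2.70, adjusted p 0.0230), led by the nucleolar GTPase gene Ns2 (276), l(3)72Dn (211) and the RNA polymerase I subunit gene Polr1D (179). Bka, Fib and Mat89Ba were not bound. Both calls were lost under most alternatives: without replicate 1 the odds ratios were 2.14 and 1.92, and without replicate 2 they were 3.09, past the threshold, and 1.88, not past it.

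Chemosensory receptor, cuticle protein and histone genes had almost no peaks. Of 180 chemosensory receptor genes, 2 were bound, Ir60b (signal 145) and Gr32a (73.4), for an odds ratio of 0.0496 (Fisher's exact test, adjusted p 2.08e-12). Gr10a, Gr10b and Gr21a were not bound. Of 121 cuticle protein genes, 1 was bound, Cpr47Eg (72.8; odds ratio 0.0370, adjusted p 1.15e-08), and Acp65Aa, Ccp84Aa and Ccp84Ab were not. Of 115 histone genes, 1 was bound, His2Av, which encodes a variant histone outside the repeated cluster (194; odds ratio 0.0390, adjusted p 1.92e-08). His1:CG31617, His1:CG33801 and His1:CG33804 lie in that cluster, where short reads map to many copies and peaks can be missed. Among genes with a housekeeping core promoter element, the cuticle and histone lists were no longer past the threshold (odds ratios 0 and 0.920). That comparison leaves out list genes without the element, so fewer genes are tested. It cannot show that the element accounts for the lack of peaks.

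**Figure D3:**
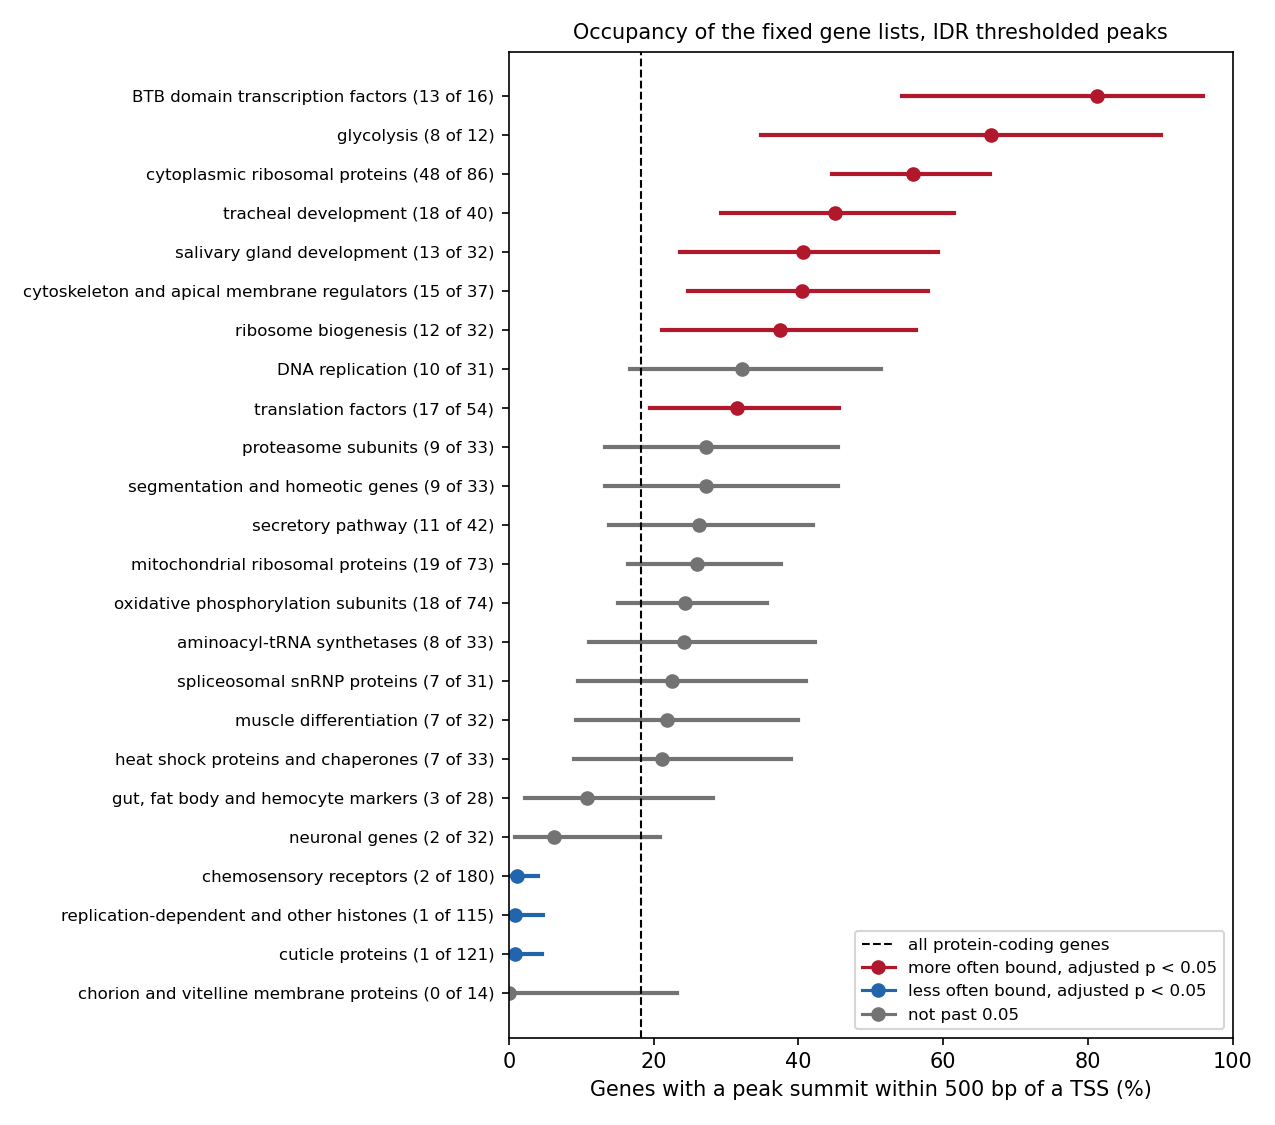
Percentage of the genes of each of 24 lists with a peak summit within 500 bp of a TSS (points) and its 95% exact interval (lines), with the 18.2% of all protein-coding genes as a dashed line. BTB transcription factors (81.3%), glycolysis (66.7%) and ribosomal proteins (55.8%) lie highest, and red and blue lists are past an adjusted p of 0.05.

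Binding was not past the threshold for the remaining 13 lists. DNA replication genes were bound at 10 of 31 (odds ratio 2.14, Fisher's exact test, adjusted p 0.117), with Prim1 (188) and dpa (157) the strongest. Segmentation and homeotic genes (9 of 33, with opa at 132 and ftz-f1 at 123) and proteasome genes (9 of 33, with Rpn3 at 115 and Rpn6 at 115) had odds ratios of 1.68. Secretory pathway genes were bound at 11 of 42 (1.59; TRAM 373 and alphaCOP 301), and mitochondrial ribosomal protein genes at 19 of 73 (1.58; mRpL41 1253, and mRpS10, which shares the peak of Art3, 869). Oxidative phosphorylation genes were bound at 18 of 74 (1.44; ND-ASHI 290 and ATPsynF 209), and aminoacyl-tRNA synthetase genes at 8 of 33 (1.44; HisRS 266 and LeuRS-m 234). Genes of spliceosomal snRNP proteins were bound at 7 of 31 (1.31; SmD3 165 and U2af50 122), muscle genes at 7 of 32 (1.26; Mef2 176 and sls 157), and chaperone genes at 7 of 33 (1.21; Hsp27 280 and Hsp83 157). Markers of gut, fat body and hemocytes were bound at 3 of 28 (0.54; ush 143 and drpr 80.6), neuronal genes at 2 of 32 (0.30; elav 319 and Nrx-1 132), and chorion genes at 0 of 14. Alternatives brought 3 of these past the threshold: secretory pathway genes in the conservative list (odds ratio 2.28), mitochondrial ribosomal protein genes with a window of 1000 bp (1.90), and neuronal genes against other housekeeping lists (0.173).

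In no list did the strength of peaks differ past the threshold from that at other bound genes. Ribosomal protein genes had a mean log2 signal of 6.90 (SD 0.55, 48 genes) against 6.89 for other bound genes (permutation p 0.923, adjusted p 0.956). BTB genes were 0.46 higher (SE 0.29, 13 genes, permutation p 0.0286, adjusted p 0.303), and proteasome genes 0.53 lower (difference −0.53, SE 0.12, 9 genes, permutation p 0.0365, adjusted p 0.303). Tracheal genes were lower as well (difference −0.34, SE 0.10, 18 genes, permutation p 0.0554, adjusted p 0.303). By this permutation test, 0 of 18 lists were past the threshold, and 2, BTB and proteasome genes, had an unadjusted p under 0.05. The BTB genes include rib itself, with the highest signal among them (1049), and the difference without rib was not computed. Mitochondrial ribosomal protein genes were 0.30 higher (permutation p 0.0862, adjusted p 0.303). That difference rose to 1.07 without replicate 1, 1.04 in the stronger 50% of peaks and 0.88 in the conservative list, past the threshold in each, and was 0.45 without replicate 2, not past it.

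Summits carried several core promoter elements more often than their own flanks 250 bp away. As 41.6% of summits lay within 200 bp of a TSS, such flanks often lie outside the core promoter. An excess of these elements can therefore follow from position alone. Ohler motif 7 (CAKCNCTR) lay within 50 bp of 6.45% of summits and in 3.19% of flanks (exact McNemar test, adjusted p 2.79e-12 over 16 motifs). The DRE (WATCGATW), which DREF binds at housekeeping promoters, lay at 3.41% against 1.35% (adjusted p 7.06e-10). Both were past the threshold under all 6 alternatives. Ohler motif 1, which M1BP binds (1.06% against 0.499%, adjusted p 0.0118), GAGA (4.82% against 3.71%, 0.0234) and the CA repeat (5.21% against 4.04%, 0.0234) were also more frequent, and the TCT initiator (10.8% against 12.9%, 0.00933) less so. These 4 calls were lost in the stronger 50% of peaks and with a window of 25 bp, and those of GAGA, the CA repeat and TCT also in the conservative list. Without replicate 1 the ratio of summits to flanks for GAGA reversed to 0.614, past the threshold in the opposite direction. That of the CA repeat was 0.911, not past it. Forkhead sites (RTAAAYA; 15.6% against 17.3%, adjusted p 0.0586) were at 1.20 there, past the threshold, but with a window of 100 bp they were past it at 0.867. Ohler motif 1 (1.5) and TCT (0.887) were not past the threshold there either. Without replicate 2, the CA repeat (1.20) and TCT (0.871) were lost, GAGA was at 1.58, and Ohler motif 6 (0.760% against 0.630%, adjusted p 0.647) rose to 2.67, past the threshold.

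At promoters, bound starts were compared with the same positions beside unbound starts. Ohler motif 7 lay at 9.56% of 2395 bound promoter summits and 4.95% of 7185 control positions (odds ratio 2.03, Fisher's exact test, adjusted p 1.31e-13). The CA repeat (odds ratio 2.69, adjusted p 6.39e-12), GAGA (2.65, 1.53e-11), the Trh site TACGTG (1.86, 1.20e-04), the DRE (1.42, 0.00280) and the TCT initiator typical of ribosomal protein genes (1.22, 0.0255) were more frequent as well. Against their own flanks, summits had no excess of the Trh site (2.80% against 2.91%, adjusted p 0.801), and TCT was less frequent there. Ohler motif 1, in excess over flanks, had no excess over unbound promoters (1.80% against 2.14%, odds ratio 0.835, Fisher's exact test, adjusted p 0.341). The TATA box (0.691, 1.09e-04) and the Inr (0.855, 0.0108) were less frequent. Without replicate 1, the odds ratios of GAGA (1.38), the Trh site (1.32), the DRE (1.15) and the TATA box (0.774) were no longer past the threshold. Without replicate 2, the same 8 motifs were past it as with both replicates. In the stronger 50% of peaks the DRE (1.32) and the TATA box (0.780) were not, while Zelda sites (0.401) and the Twist E-box (1.46) were.

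An open search for short words at bound promoters gave GAGA-like and CA-rich words. Of 8192 7-mers, 249 were more frequent at bound promoter summits and 78 less frequent. AGCGAGA was at 3.88% of summits against 0.974% of controls (odds ratio 4.11, Fisher's exact test, adjusted p 1.46e-14). CTCGCTC (odds ratio 3.48), CACACAC (2.31), CGCACAC (2.68), CTCTCGC (3.40), CTCGCAC (3.47), CGCTCGC (2.79), CTCTCTC (2.65), CGCACGC (3.35) and ACACACG (2.86) followed. The mean GC content was 43.5% at these summits and 41.5% at the controls. Without replicate 1 only 26 of the 7-mers were past the threshold, against 245 without replicate 2, and CTCGCAC (2.43), CGCTCGC (1.77), CTCTCTC (1.38) and ACACACG (1.35) were lost.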

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

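The count in this part and the arm ratio with it were chosen only after the result was seen, and no explanation was tested. The ranked regions of the series held 4778 with a score of 830 or more, which is the score of every peak in the thresholded list, yet that list holds 4606. The 172 left out are listed here because they are data that no planned comparison used, and how the thresholded list was filtered fixes their number. Most were on 3R (106) and 2L (48), and they came in groups. With them counted, the ratio of peaks to TSSs on 3R was 0.984 instead of 0.923, so the lower share of 3R rests on their absence. On 2L, 9 lay between 12003273 and 12012428, with a highest signal of 1054, and 7 between 472447 and 482004, with 1045. The latter stretch spans the start of ush at 476220, a gene of the tracheal list. On 3R, 12 lay between 16224508 and 16255273, with a highest signal of 302. The deposited description names a further annotation as an input of the thresholded list, without saying what it holds, and no biological explanation was tested.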

How the results depend on the processing

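The alternatives with the 2000 strongest peaks of each replicate, and with all ranked regions past the score, were chosen only after the result was seen, and the others were planned. The promoter share kept its direction and stayed past the threshold under 7 alternatives (41.6% to 63.0%), as did the binding of ribosomal protein genes (odds ratio 2.93 to 7.76), BTB genes (8.36 to 41.6) and chemosensory receptor genes (0 to 0.102) under 11. No alternative allowed for the number of annotated starts per gene. For the values below, the cause was not tested unless stated.

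Leaving out each replicate in turn gave 2181 to 3082 peaks, 1 to 4 called arms, 6 to 10 called gene lists, 0 to 1 list with a called difference in signal, 4 to 8 motifs called at promoters and 26 to 245 7-mers. Odds ratios ranged from 1.47 to 4.04 for tracheal genes, 1.92 to 3.05 for salivary gland genes, 2.30 to 3.23 for cytoskeleton genes, 1.88 to 1.92 for ribosome biogenesis and 2.14 to 3.09 for translation factors. The ratio of summits to flanks ranged from 0.614 to 1.58 for GAGA, 0.911 to 1.20 for the CA repeat and 0.924 to 1.20 for forkhead sites, and each changed direction without replicate 1. GAGA and forkhead sites were past the threshold in that new direction and the CA repeat was not. The cause was not tested for motifs. For gene lists, equal numbers of peaks left the calls of tracheal (odds ratio 3.91), salivary gland (3.57), cytoskeleton (3.38) and translation factor genes (2.89) in replicate 1, so that a list of 2000 peaks sufficed to call them there, but not in replicate 2.

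With an overlap of at least 50% of both peaks, 42.5% of replicate 1 peaks and 60.1% of replicate 2 peaks were shared. With summits within 100 bp these were 45.1% and 63.8%, and for the 1000 strongest peaks of each they were 64.3% and 64.1%. The correlation of signals was 0.71 in the conservative list and 0.61 with summits within 100 bp. Against assembled bases, the ratio of 2L reversed to 1.09. With all ranked regions past the score, 4 arms were called, and 3R (0.984) and 2R (1.05) were not.

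In the conservative list, tracheal genes (2.18) and ribosome biogenesis (2.31) lost their call, 1 list differed in signal, 3 motifs differed from flanks and 215 7-mers were called. In the stronger 50% of peaks, 7 lists were called, and ribosome biogenesis (1.78), salivary gland (2.57), tracheal (1.93) and translation factor genes (2.21) were not, with 1 list differing in signal, 2 motifs from flanks and 85 7-mers. Fewer peaks were tested there. A motif window of 25 bp left 2 motifs, and 8-mers gave 121 calls, where single words are rarer.

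With a window of 1000 bp, translation factors had an odds ratio of 1.82, and with the nearest TSS alone 1.92, with ribosome biogenesis at 1.69, none past the threshold. Among genes with a core promoter element, which leaves fewer genes to test, 3 lists were called, and these were not: cuticle (0), cytoskeleton (1.14), glycolysis (19.4), histones (0.920), ribosome biogenesis (3.05), salivary gland (2.31), tracheal (3.17) and translation factors (1.98). Against other housekeeping lists, 7 were called, without cytoskeleton (1.77), ribosome biogenesis (1.55), salivary gland (1.77), tracheal (2.12) and translation factors (1.26). With the 2000 strongest peaks of replicate 1, ribosome biogenesis (2.10) lost its call. With those of replicate 2, 6 lists were called, without cytoskeleton (2.37), ribosome biogenesis (1.98), salivary gland (1.98), tracheal (1.51) and translation factors (1.95).

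Of 263 values for single lists, 226 kept their side of the threshold, and of 81 for signal 78 did. So did 76 of 96 for motifs against flanks, 83 of 96 at promoters, and 35 of 40 for the named 7-mers. Values not past the threshold could change direction and still count as kept, as for proteasome genes (odds ratio 1.68, and 0.669 without replicate 2). Many of these lists were never called. Among called lists, ribosome biogenesis kept its call under 2 of 11 alternatives, translation factors under 4 and tracheal genes under 5. The signal test gave no value for a list with fewer than 5 bound genes under an alternative. Depth is unknown, so how many weak sites were missed cannot be said.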

Other observations

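The tests of tracheal genes between the replicates, the GC content of peaks with CAGTGG, the test of weak regions around rib, the signal ratios of single housekeeping lists, the counts of peaks per gene and the GC content by rank were chosen only after the result was seen. The other tests were set before the values they measure were seen, on patterns noticed in these data.

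Peaks crowded along some genes, of which those named here were picked after their values were seen. Within a gene and 1 kb on either side, Eip75B (3L 17950953 to 18064696), which encodes a nuclear receptor induced by ecdysone, held 33 peaks, the highest count of any protein-coding gene, where its length gives 3.88 at the average density. The ecdysone receptor gene EcR held 15 (2.79 from length), and Eip74EF, an ecdysone-induced ETS factor, 12 (2.10). Other genes with many peaks were bun, a regulator of growth (18, 3.12 from length), shn, a zinc finger factor of the Dpp pathway (16, 2.02), sbb (15, 2.72), brat, a repressor of translation (14, 1.61), CG1677 (13, 4.24), the kinase gene Tlk (12, 2.40), CHES-1-like, a forkhead factor (11, 0.973), SNF4Agamma, a subunit of AMP kinase (11, 2.53), the overlapping CG46467 and Glut4EF (11 each, 3.89 and 4.11), jing (10, 4.08) and lola (10, 2.12). Short genes with many peaks were rib itself (14 in 11.3 kb, 0.446 from length), CG14434 (14 in 15.3 kb, 0.579 from length), HmgD (10, 0.578) and PRAS40 (10, 0.607), while hth, which is longer than Eip75B, held 10 (4.49). In all, 20 of 13968 protein-coding genes held 10 or more. Peaks were counted by summit here too. No list of ecdysone genes was tested.

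The hexamer CAGTGG may mark a directional site at the strongest peaks. Of the strongest 500 peaks, 498 were kept after leaving out the weaker of summits so close that they could share sequence. At 20 to 100 bp from the summit, 83 (16.7%) had the hexamer reading 5′ to 3′ toward it and 17 (3.41%) away. The hexamer had been picked from these peaks, so orientation was tested in the next 500, where 35 peaks had it toward the summit alone and 15 away from it alone (exact binomial p 0.00660). That argues against a chance orientation in the peaks used to find it. Summits close to one of the strongest 500 were not left out of the next 500, so some sequence may be shared. Of the 83 peaks, 1 shared a 30-mer with another place in the assembly (1.20%, exact interval 0.0305% to 6.53%), which argues against exact copies of a repeat. Diverged copies were not searched for. The summits of these 83 peaks had a mean GC content of 30.9% (SD 12.1), against 46.5% and 44.6% at 100 bp to either side. Those of the other 415 peaks had 37.0% (SD 13.3), against 43.9% and 43.6%, so a lower GC content at the summit was not confined to peaks with the hexamer. Over all peaks, GC at the summit was 32.6% in the strongest 100 and 45.6% at ranks 2001 to 4606. Whether the rib protein or another protein reads the hexamer stays open, and no biological explanation was tested.

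More ribosomal protein genes were bound in replicate 2 alone (20) than in replicate 1 alone (5), while for tracheal genes the counts were 0 and 9. Among genes outside the ribosomal protein list, 361 were bound in replicate 2 alone and 693 in replicate 1 alone. The log2 ratio of replicate 2 to replicate 1 signal at ribosomal protein genes lay 0.44 above that at other bound genes (bootstrap interval 0.12 to 0.82, permutation p 0.00017, adjusted p 0.00306). Fewer peaks in replicate 2 would lower the count bound there alone, so that explanation could not give the excess of ribosomal protein genes. The ratio comes from the same 2 replicates and is not independent of these counts. For the 58 bound genes of 5 other housekeeping lists, the shift was 0.0575 (interval −0.15 to 0.20), whose upper bound is narrowly under the 0.22 that a rise at all housekeeping promoters was taken to need. That argues against a rise at all of these promoters, but not against a rise at some: oxidative phosphorylation genes lay 0.27 higher (interval −0.44 to 0.66) and mitochondrial ribosomal protein genes, outside the pool, 0.26 higher (0.01 to 0.46), with adjusted p 0.396 for both (permutation test). For tracheal genes the shift was −0.32 (interval −0.65 to −0.21, 17 genes), with a permutation p of 0.0875 and an adjusted p of 0.396. Against the split of other genes, the counts of 0 and 9 had an adjusted p of 0.124 over 8 lists (Fisher's exact test). With the 2000 strongest peaks of each replicate, 6 tracheal genes were bound in replicate 1 alone and 0 in replicate 2 alone (Fisher's exact test against other genes, adjusted p 0.0181 over 4 lists). Of these 3 tests 1 passed, so for tracheal genes the lower number of peaks and a lower relative signal cannot be told apart. A different mix of embryo ages within 0 to 24 h could give such a contrast. The labels give no ages per replicate, so it stays untested, and no biological explanation was tested.

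The crowd of peaks at rib may come in part from extra copies. Regions under the threshold within 20 kb of rib and away from its peaks (20 regions) had a median signal of 34.2, against a median of 20.9 over 10000 random windows, a ratio of 1.64, and 99.68% of the windows were lower. Copies of the region in the transgene would raise weak signal in this way. The windows were placed at random and not matched for the number of peaks. The test therefore cannot separate copies from a region dense in peaks. A strong regulatory region at rib, bound by its own product, stays open as well, and no biological explanation was tested.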
